A study of Mus musculus with 5 samples.

How the data were processed

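Single nuclei from the superficial superior colliculus, the visual layers of a midbrain structure that receives input from the retina, were profiled in 5 libraries of mice aged 2 to 4 months. Per the labels' protocols, the tissue was dissected from slices of 1 mm by knife cuts, nuclei were purified on a density gradient, and droplet libraries were made with a 3' kit that reads each transcript near its poly(A) end and tags every molecule with a unique molecular identifier (UMI). The deposited files hold raw UMI counts per gene and barcode, whole numbers that were not normalized. Per the submitters' processing notes, the counts were made with Cell Ranger 3.0.2. The genome build, the annotation, and how the counting treated strand and introns are not given in the sources used here. The labels name 2 sequencing instruments, a NextSeq and a NovaSeq, without saying which library ran on which, and a mean depth of 35998 reads per cell. The files list 22613 genes, 21784 of them protein-coding in GENCODE M21 (GRCm38), the annotation used here for coordinates and strands; 22503 of the gene identifiers were found in it. Coordinates are therefore those that GENCODE M21 gives for the identifiers in the files. Most long non-coding RNAs, Xist and Tsix among them, were not analysed here.

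The 5 libraries held 57342 barcodes. A barcode was kept as a nucleus with at least 400 detected genes and under 5% of its UMIs from mitochondrially encoded genes, which removed 2984 barcodes for few genes and 22227 for their mitochondrial share. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the highest-scoring barcodes were removed up to the rate expected from loading (0.8% per 1000 barcodes), 3160 in all. The 28971 nuclei kept were scaled to 10000 counts, log-transformed and clustered on the 3000 most variable genes with 30 principal components, 20 nearest neighbours and the Leiden method at resolution 1.0 (leidenalg 0.10.2, seed 0). The genes of the fixed lists, other than those that are also markers, and all mitochondrially encoded genes were left out of the clustering. Markers and genes outside the lists could take part in it, so some genes reported on helped to define the clusters. Each cluster took the class whose fixed markers were highest, after 20 CPM (UMI counts scaled to a total of 1e6) were added to each level. A named cluster needed at least 3 markers detected at 10 CPM or more, and a non-neuronal one also a mean log2 fold of at least 1. Neuronal clusters had no minimum fold. An excitatory cluster needed Slc17a6 at 3 or more times the mean of Gad1, Gad2 and Slc32a1, and an inhibitory cluster the reverse. Clusters with leading markers of 2 classes were called mixed and left out. These naming thresholds were set after the nuclei had been clustered. They kept out of the classes a mean of 8.18% of nuclei as mixed and 0.335% as unnamed in the female libraries, and 0.318% and 0.413% in the male ones. No annotation of the nuclei by the authors was used here, so the class names are rebuilt from markers.

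Counts were summed per library and class, and the library was the unit of replication throughout. The sums were tested with the quasi-likelihood method of edgeR 4.0.16 (robust, TMM scaling, default expression filter) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Excitatory and inhibitory neurons were compared with the library as a block, since both sums of a library come from the same nuclei suspension. Female and male libraries were compared within each class that had at least 50 nuclei in every library, and the interaction of sex with neuron class was tested in the blocked model. Shares of classes were tested with edgeR on numbers of nuclei and with a two-sided exact permutation test. With 3 female and 2 male libraries there are 10 possible splits, so that test cannot give a p under 0.1. DESeq2 1.42.0 (Wald test) was the alternative tool. The number of animals behind a library is not stated, so p-values measure only the spread between these libraries, part of which may be technical. Residual degrees of freedom were 4 for the comparison of neuron classes and 3 for each comparison of the sexes.

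The samples, tests, markers, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The 25 lists comprised 13 neuronal ones (neuropeptides, neuropeptide receptors, calcium-binding proteins, ionotropic and metabotropic glutamate receptors, GABA and glycine receptors, acetylcholine receptors, monoamine receptors, voltage-gated potassium channels, voltage-gated sodium, calcium and HCN channels, neuronal transcription factors, synaptic adhesion genes, and cadherins) and 12 others for the sexes (Y-linked, X inactivation RNAs, X-linked genes that escape inactivation, sex steroid receptors, immediate early, circadian clock, heat shock, glucocorticoid response, mitochondrially encoded, cytosolic ribosomal protein, nuclear oxidative phosphorylation, and nuclear-retained long non-coding RNAs). Lists were tested against the other genes with camera in limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation. Named genes were, per neuronal list, up to 3 each way with the smallest adjusted p that moved the same way in every library, and up to 5 each way outside the lists with the largest fold, at 10 CPM or more in the higher class and not used in the clustering. Between the sexes the rule took every measured member of the Y-linked and X-linked lists, up to 5 other genes each way per class, and other list genes past the threshold. Neurons of each class were clustered again with genes centred within libraries, and the subcluster rule took genes at 50 CPM or more, at least 4 times the median subcluster and highest in the same subcluster in every library with at least 20 nuclei of it.

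The tests were checked on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For excitatory against inhibitory neurons, over 13336 genes, 97 and 100 were recovered. For the sexes, 32 and 92 were recovered in excitatory neurons and 33 and 91 in inhibitory neurons. In astrocytes it was 6 and 62, and in oligodendrocytes 3 and 36. A 2-fold difference between the sexes was thus mostly missed in the simulated data. Simulated counts were drawn independently, with no grouping of libraries, so recovery in the real data may differ. For the interaction, 73 and 93 were recovered. False calls numbered 1 to 10 per comparison. Depth entered the sums as 2388943 to 11694711 UMIs per library and neuron class, 339910 to 1929578 for astrocytes and 211952 to 817917 for oligodendrocytes. Confidence intervals of shares are 95% Wilson intervals and cover counting error only. Where a count was 0, the limit given is the share or level that 3 counts would have made.

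The alternatives were DESeq2's size factors or its test, no expression filter beyond a total of 1 count, the library block left out or added, classes taken from each nucleus's own transmitter UMIs, clustering on all variable genes, no doublet removal, at least 800 genes per nucleus, thinning to 1000 UMIs, resolution 2.0, no centring, and each library left out in turn. Chosen after seeing the data were runs with no mitochondrial filter, without barcodes shared by 2 libraries, with genes centred within libraries, with each library clustered alone, without clusters led by another class's markers, with a term for female libraries 2 and 3, and with clusters compared by number. With the term for female libraries 2 and 3, the sex difference is that of female library 1 alone against the 2 male libraries. Thinning and the minimum of 800 genes were not run for oligodendrocytes, since a library then had fewer than 50 nuclei.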

Results

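The series set out to map cell types of the mouse superficial superior colliculus from gene expression in single nuclei. Of the 5 libraries, 3 came from female and 2 from male mice. Female library 1 carried Chat-Cre, a Cre driver of the choline acetyltransferase gene, with an H2b-TRAP reporter, and the other 4 carried Chat-GFP. Before filtering, the libraries held 14904, 5155 and 5024 barcodes for females 1, 2 and 3 and 16510 and 15749 for males 1 and 2. Their total UMI counts were 38462382, 12999342, 11904615, 23487525 and 32474977. The median share of UMIs from mitochondrially encoded genes was 3.49% in female library 1, 0.204% and 0.239% in female libraries 2 and 3, and 7.56% and 7.24% in the male libraries. That share was at or above the limit of 5% in 34.1%, 0.116% and 0.0995% of the female barcodes and 62.1% and 62.03% of the male ones. These percentages include barcodes removed for few genes. Among the other barcodes, the filter on that share removed 5082, 6 and 5 from the female libraries and 7766 and 9368 from the male ones. After all filters 8559, 4923, 4815, 5464 and 5210 nuclei remained, with median depths of 2646, 2017, 1969, 1587 and 2316 UMIs and total depths of 24287114, 12147488, 11055845, 9585210 and 13399714 UMIs.

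Neurons made up most of the nuclei. Inhibitory-like neurons, which held the GABA transporter Slc32a1 at 614 ± 172 CPM and the GABA-synthesizing enzyme Gad2 at 415 ± 60.4 CPM, formed 41.98 ± 6.34% of nuclei (mean ± SD, n = 5 libraries). Excitatory-like neurons, which held the vesicular glutamate transporter Slc17a6 at 317 ± 54.01 CPM against 34.6 ± 12.1 CPM in inhibitory-like neurons, formed 25.1 ± 10.9%. Astrocyte-like nuclei (11.1 ± 4.46%) held the heparan sulfate proteoglycan Gpc5 at 7110.0 ± 499.6 CPM and the glutamate transporter Slc1a2 at 3317 ± 191 CPM. Oligodendrocyte-like nuclei (9.51 ± 5.11%) held the myelin basic protein gene Mbp at 3358 ± 262 CPM. Oligodendrocyte precursor-like nuclei (2.32 ± 0.432%) held the growth factor receptor Pdgfra at 1243 ± 262 CPM. Microglia-like nuclei formed 2.07 ± 0.706%. Fibroblast-like nuclei formed 1.55 ± 0.94%, endothelial-like 0.358 ± 0.353%, mural-like 0.247 ± 0.159% and border macrophage-like 0.241 ± 0.153%. A hemoglobin-led cluster formed 0.165 ± 0.346%, mixed clusters 5.04 ± 6.503% and unnamed ones 0.366 ± 0.217%. The nuclei fell into 36 clusters. The mitochondrial filter removed far more barcodes from female library 1 and the male libraries than from the other 2, and depth per nucleus differed as given, so shares carry both.

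**Figure D1:**
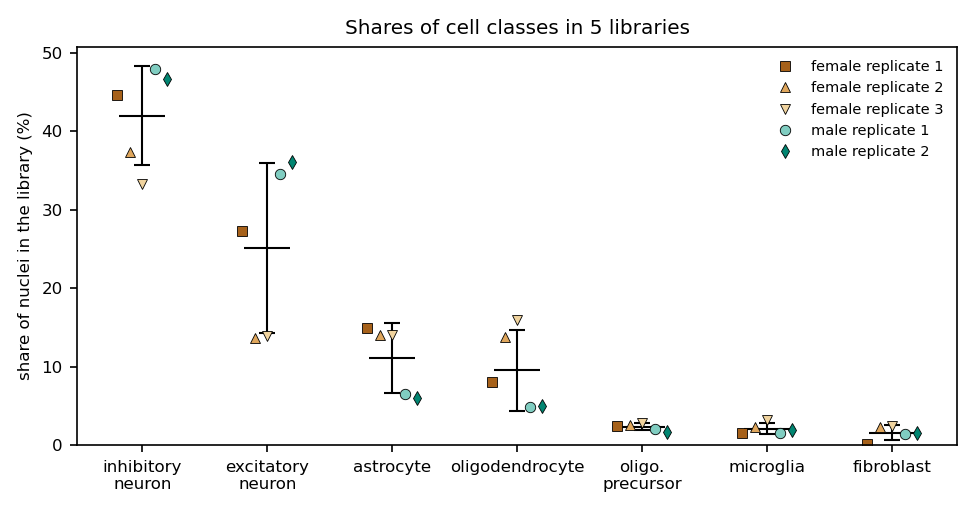
Share of nuclei in each of the 7 most frequent named classes (y axis, percent of the nuclei of a library); points are the 5 libraries and bars the mean with SD. Astrocyte-like nuclei formed 14.3 ± 0.515% of the female and 6.205 ± 0.387% of the male libraries.

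The main comparison asked how the excitatory and inhibitory neurons of this region differ outside their transmitter genes. Excitatory neurons held more of the tachykinin receptor gene Tacr1 (78.7 ± 8.78 against 9.25 ± 2.25 CPM, log2 fold 3.11 ± 0.09 SE, n = 5 libraries each). They also held more of the axon guidance receptor gene Robo3 (40.7 ± 11.6 against 2.81 ± 1.87 CPM, 3.90 ± 0.15). Inhibitory neurons held more of the presynaptic adhesion gene Nrxn3 (6411 ± 918 against 1313 ± 131 CPM, log2 fold -2.28 ± 0.04), the transcription factor gene Zfhx3 (1121 ± 159 against 283 ± 47.2 CPM, -1.99 ± 0.04) and the nicotinic receptor gene Chrna3 (73.8 ± 36.2 against 5.53 ± 1.66 CPM, -3.59 ± 0.11). All 5 moved the same way in every library, as the rule for naming genes required. The adjusted p by edgeR's quasi-likelihood test was 5.883e-22 for Tacr1 and 2.73e-28 for Nrxn3. In all, 4569 of 13336 genes passed, 2127 higher in excitatory and 2442 higher in inhibitory neurons. Among the 10655 genes not used in clustering 3487 passed (1650 and 1837). Without the markers that set the classes, 4529 of 13261 passed (2108 and 2421). DESeq2 called 2687 genes, 1423 higher in excitatory and 1264 in inhibitory neurons, of which 2662 were among the 4569.

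Signalling peptides and their receptors were divided between the classes. Of 15 measured neuropeptide genes, 8 were higher in excitatory and 3 in inhibitory neurons, among them Cartpt (cocaine- and amphetamine-regulated transcript, chromosome 13 from 99898489 to 99901091; 60.8 ± 20.3 against 11.7 ± 5.59 CPM, log2 fold 2.43 ± 0.09) and Adcyap1 (the peptide PACAP; 24.9 ± 4.11 against 2.60 ± 1.48 CPM, 3.19 ± 0.19) on the excitatory side. Pnoc, the precursor of nociceptin, was higher in inhibitory neurons (63.3 ± 33.3 against 8.51 ± 4.44 CPM, -2.80 ± 0.11), as was Npy, neuropeptide Y (22.4 ± 14.6 against 5.45 ± 2.39 CPM, -1.96 ± 0.15). Somatostatin, Sst, passed in the inhibitory direction (226 ± 92.5 against 45.1 ± 5.18 CPM, -2.10 ± 0.29, adjusted p = 0.00721), a call that depended on the clusters. Without the clusters led by another class's markers, its fold was -0.20 (adjusted p = 0.744 by edgeR). An inhibitory cluster led by Sst was 1 of those left out, so a lower inhibitory level follows by construction. The adjusted p of Sst ranged from 1.087e-42 to 0.744 over the alternatives. As a list, neuropeptides stood toward excitatory neurons by camera (adjusted p = 0.0113), a call lost with an estimated correlation (adjusted p = 0.0929) and without the mitochondrial filter (0.0968; 8.414e-05 to 0.178 over the alternatives). Neuropeptide receptors were split, 8 and 6 of 22 (camera adjusted p = 0.129). The cholecystokinin receptor gene Cckbr was higher in excitatory neurons (log2 fold 1.98 ± 0.19), while the orexin receptor gene Hcrtr2 (69.5 ± 3.29 against 27.6 ± 2.64 CPM, -1.34 ± 0.07) and the tachykinin receptor gene Tacr3 (-1.03 ± 0.12) were higher in inhibitory neurons. Of 11 calcium-binding protein genes 6 were higher in excitatory neurons, with Necab1 at 125 ± 18.8 against 34 ± 4.91 CPM (1.89 ± 0.05), and 1, Cabp1, in inhibitory neurons (-0.96 ± 0.06). The list passed at either correlation (adjusted p = 6.599e-04 preset, adjusted p = 0.0481 with an estimated correlation).

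Receptors for fast transmitters differed in direction by family. Of 18 GABA and glycine receptor genes 14 were higher in excitatory neurons and 2 in inhibitory neurons (camera adjusted p = 1.365e-11, adjusted p = 0.0104 with an estimated correlation). The subunit gene Gabrb2 (409.7 ± 32.1 against 231 ± 25.8 CPM, log2 fold 0.83 ± 0.04) was higher in excitatory neurons. The glycine receptor gene Glra2 was higher in inhibitory neurons (60.4 ± 7.58 against 35.7 ± 7.16 CPM, -0.68 ± 0.16, adjusted p = 0.0249). Without male library 2 the adjusted p was 0.0756, and over the alternatives it ran from 1.27e-12 to 0.47. Acetylcholine receptors went the other way, 2 of 10 higher in excitatory and 5 in inhibitory neurons (camera adjusted p = 3.592e-06, adjusted p = 0.0274 with an estimated correlation). The nicotinic subunit genes Chrnb3 (36.8 ± 6.004 against 3.61 ± 0.894 CPM, -3.24 ± 0.13) and Chrna6 (33.05 ± 11.2 against 2.56 ± 0.503 CPM, -3.47 ± 0.14) were higher in inhibitory neurons, and the muscarinic receptor gene Chrm3 in excitatory neurons (841 ± 111 against 478 ± 78.7 CPM, 0.82 ± 0.04). Ionotropic glutamate receptors were split 7 and 6 of 17 (camera adjusted p = 0.735). The kainate receptor gene Grik3 (log2 fold 1.76 ± 0.06) and the AMPA receptor gene Gria2 (0.64 ± 0.04) were on the excitatory side, and Gria1 (1014 ± 220.1 against 359 ± 112 CPM, -1.51 ± 0.06) and Grik2 (-0.97 ± 0.04) on the inhibitory side. Metabotropic glutamate receptors were split 3 and 3 of 7 (camera adjusted p = 0.915), with Grm3 higher in inhibitory neurons (-1.41 ± 0.11). The mean of this list lay above 0 and its median below. Of 20 monoamine receptor genes 6 and 9 passed (camera adjusted p = 0.0635, adjusted p = 0.134 with an estimated correlation, 0.0266 without male library 2 and 0.0266 to 0.211 over all alternatives). The serotonin receptor gene Htr1b was higher in excitatory neurons (1.28 ± 0.15) and the dopamine receptor gene Drd1 in inhibitory neurons (16.6 ± 7.83 against 2.18 ± 1.04 CPM, -2.71 ± 0.19).

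Voltage-gated channels stood mostly toward excitatory neurons. Of 27 potassium channel genes 17 were higher there and 3 in inhibitory neurons (camera adjusted p = 1.304e-12, adjusted p = 0.0104 with an estimated correlation). Kcnh5, an ether-a-go-go type channel, was at 164 ± 14.6 against 53.2 ± 5.08 CPM (log2 fold 1.63 ± 0.05), and Kcnip1, a modulator of A-type channels that overlaps Kcnmb1 on the other strand, was higher in inhibitory neurons (-1.29 ± 0.05). Of 23 sodium, calcium and HCN channel genes 11 and 2 passed (camera adjusted p = 8.587e-06, adjusted p = 0.0274 with an estimated correlation). The sodium channel subunit gene Scn4b was higher in excitatory neurons (1.63 ± 0.14), while the calcium channel subunit genes Cacna2d2 (229.5 ± 11.1 against 121 ± 6.94 CPM, -0.92 ± 0.05) and Cacna2d3 (-0.44 ± 0.04) were higher in inhibitory neurons. The direction of Cacna2d3 turned to 0.23 (adjusted p = 7.079e-04) without the clusters led by another class's markers, and its adjusted p ran from 5.32e-26 to 0.149 over the alternatives.

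Transcription factors and surface molecules marked both classes. Of 36 transcription factor genes 14 were higher in excitatory and 17 in inhibitory neurons. Ebf3 (204 ± 23.1 against 42.1 ± 6.15 CPM, log2 fold 2.28 ± 0.06) and Barhl2 (2.72 ± 0.26) were on the excitatory side. Pax7 (48.6 ± 11.9 against 3.45 ± 0.974 CPM, -3.78 ± 0.11) and Tal1 (48.5 ± 15.8 against 5.71 ± 1.62 CPM, -2.96 ± 0.11) were on the inhibitory side. Camera placed this list toward inhibitory neurons (adjusted p = 0.00913), in the direction of its median log2 fold (-0.22) and against its mean (0.07). The call was lost with an estimated correlation (adjusted p = 0.134), and without female library 2 the direction turned (adjusted p = 0.935; 3.478e-04 to 0.949 over the alternatives). Of 41 synaptic adhesion genes 22 and 9 passed (camera adjusted p = 0.0232, adjusted p = 0.114 with an estimated correlation; 0.0742 without female library 2 and 1.845e-04 to 0.261 over the alternatives). The neuroligin gene Nlgn1 was higher in excitatory neurons (3644 ± 378 against 2145 ± 285 CPM, 0.77 ± 0.03), and C1ql3, a secreted synaptic organizer, in inhibitory neurons (48.4 ± 14.9 against 5.25 ± 2.75 CPM, -3.08 ± 0.12). Cadherins were split 8 and 10 of 20 (camera adjusted p = 0.899), with Cdh13 (996 ± 141 against 347.5 ± 51.4 CPM, 1.52 ± 0.04) and Cdh7 (1.62 ± 0.05) higher in excitatory neurons and Cdh22 (-1.64 ± 0.07) in inhibitory neurons. Outside the lists the largest folds on the inhibitory side were those of the matrix protein gene Smoc2 (-3.93 ± 0.22), the GABA receptor gene Gabrr1 (-3.37 ± 0.21) and the acid-sensing channel gene Asic4 (103 ± 8.77 against 10.4 ± 2.62 CPM, -3.22 ± 0.08), together with the predicted genes Gm45716 and Gm19410. On the excitatory side they were those of Robo3, Tspan11 (3.78 ± 0.18), Them7 (3.44 ± 0.22), Npffr2 (3.35 ± 0.24) and Samd3 (3.24 ± 0.15). Adjusted over the list alone, the counts were 7 and 7 for ionotropic and 3 and 4 for metabotropic glutamate receptors. They were 18 and 3 for potassium channels, 13 and 2 for sodium, calcium and HCN channels, 14 and 19 for transcription factors and 23 and 9 for synaptic adhesion genes. They did not change for the other 7 lists.

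**Figure D2:**
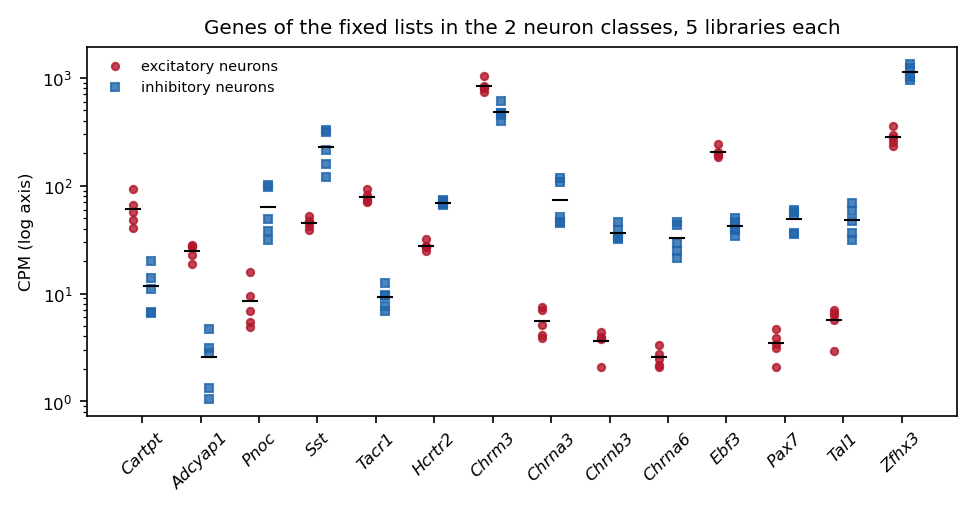
Level of genes of the fixed lists (y axis, CPM on a log axis) in the excitatory and inhibitory neurons of the 5 libraries; each point is a library and each line a mean. Tacr1 lay at 78.7 CPM in excitatory and 9.25 CPM in inhibitory neurons, and Chrna3 at 5.53 and 73.8 CPM.

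Clustered again, the neurons fell into 17 excitatory subclusters (E) and 28 inhibitory ones (I), of which 30 had at least 20 nuclei in every library. Since list genes other than markers took no part in the clustering, where they were high was not fixed by it. No test was run over subclusters. Sst was highest in I6 at 2256 ± 1117 CPM (n = 5 libraries), against 31.7 CPM in the median subcluster and 1716 in I15. Among excitatory subclusters, Vip (vasoactive intestinal peptide) was highest in E3 at 246.5 ± 84.2 CPM (median subcluster 2.09), Cartpt in E2 at 334 ± 148 CPM (8.90), Grp (gastrin-releasing peptide) in E12 at 123 ± 77.7 CPM (1.53) and Tacr1 in E6 at 198 ± 32.6 CPM (19.6). The calcium-binding protein genes Calb1 and Necab1 were highest in E3 (195 ± 38.5 CPM) and E5 (357.5 ± 49.9 CPM). The transcription factor gene Ebf2 was highest in E4 at 618.5 ± 77.3 CPM against 6.93 in the median subcluster.

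Apart from Sst, the genes that met the rule in inhibitory subclusters were those of receptors and transcription factors. Hcrtr2 was highest in I5 (304.5 ± 33.5 CPM, median subcluster 38.8), Tacr3 and the mu-opioid receptor gene Oprm1 both in I3 (108 ± 13.3 and 363 ± 91.3 CPM), the somatostatin receptor gene Sstr2 in I21 (86.8 ± 48.1 CPM), Chrnb3 in I1 (207 ± 40.9 CPM, median subcluster 2.38) and the nicotinic receptor gene Chrna7 in I24 (436 ± 106 CPM). The transcription factor genes Zfhx3 (3181 ± 322 CPM), Zfhx4 (761 ± 143 CPM) and Maf (952 ± 96.5 CPM) were all highest in I13, Meis1 in I7 (493 ± 63.6 CPM) and Meis2 in I11 (2018 ± 195 CPM). In all, 26 genes met the rule. Others were highest in subclusters with fewer than 20 nuclei in 1 or more libraries: Adcyap1, Tcf7l2 and Tcf4 in excitatory ones with 20 or more in 3 libraries, Nfia and Satb1 in I27 with that many in 4, and Ebf3 in I28 with that many in 2. Without centring within libraries 31 genes met the rule over 51 subclusters, at resolution 2.0 it was 22 over 55, and with all variable genes 23 over 50. Against their class, subcluster I14 was led by Slc17a6, E17 by the complement gene C1qb and E1, E6 and I5 by the hemoglobin gene Hbb-bs. The leading genes of I22 included Slc17a6, and those of I17, I20 and I26 included Hbb-bs, so values of these subclusters are those of a number and not of a type.

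The sexes were compared first by the make-up of the tissue. Astrocyte-like nuclei formed 14.3 ± 0.515% of the 3 female and 6.205 ± 0.387% of the 2 male libraries, a log2 ratio of 1.21 ± 0.19 (adjusted p = 0.0276 by edgeR over 10 classes), higher in 3 of 3 female libraries. The exact permutation test gave p = 0.1, the smallest that 10 splits allow. Most astrocytes of female libraries 2 and 3 lay in cluster 9, those of female library 1 and male library 1 in cluster 4, and those of male library 2 in both. The call held without female library 1 (1.18, adjusted p = 9.03e-06), when 10 of 10 classes passed. It was lost without female library 2 (1.22, 0.283), female library 3 (1.22, 0.148), male library 1 (1.27, 0.267) or male library 2 (1.14, 0.346), when 0 classes passed by edgeR. Over the alternatives the adjusted p ran from 9.03e-06 to 0.495. No other class passed in the full comparison. Oligodendrocyte-like nuclei formed 12.6 ± 4.11% of female and 4.90 ± 0.152% of male libraries (1.36 ± 0.38, adjusted p = 0.107), excitatory-like neurons 18.3 ± 7.78% and 35.3 ± 1.04% (-0.95 ± 0.40, adjusted p = 0.239), and inhibitory-like neurons 38.4 ± 5.75% and 47.3 ± 0.939% (-0.30 ± 0.22, adjusted p = 0.351). The ratio in neurons was not stable. For excitatory-like neurons it was 0.04 without doublet removal, -0.05 without shared barcodes and 0.37 without the mitochondrial filter. At 800 genes per nucleus it was -0.49 (adjusted p = 0.0322 by edgeR). The inhibitory ratio was 0.33 without the mitochondrial filter. Naming changed too: in the full run mixed nuclei came mostly from female libraries. Without shared barcodes a mixed cluster held 2844 nuclei, 1398 and 1288 of them from the male libraries. Without the mitochondrial filter a mixed cluster held 5727, of which 1446 and 1587 were male. The adjusted p was 0.239 for oligodendrocyte precursor-like and endothelial-like nuclei, 0.29 for mural-like, 0.409 for microglia-like and 0.933 for fibroblast-like and border macrophage-like nuclei. Without the mitochondrial filter the astrocyte ratio was 0.64 (adjusted p = 0.0331), and with at least 800 genes per nucleus 2.43 (0.0322). In the run without that filter, a cluster of 5566 barcodes stayed unnamed, 2509 and 3022 of them from male libraries 1 and 2. Its median mitochondrial share was 38.5%. Beside mitochondrially encoded genes, its leading genes were Ndrg2, Mt3, Mt1, Aldoc and Dbi. These barcodes were in no named class, and whether astrocytes were among them was not tested. The astrocyte ratio of that run does not cover them and could differ with them.

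Within neurons, the sexes were compared in the 11 named clusters with at least 50 nuclei in every library. Clusters went by number because clusters 1, 2, 7 and 21 had more markers of another class than of their own among their leading genes (Dcn, Chat and C1ql1). Clusters 1 and 21 are among the 11, and clusters 2 and 7 are not. All 11 come from the same 5 libraries, so they are not independent of each other. The Y-linked genes were the clearest difference. Eif2s3y, a translation initiation factor gene, had 0 UMIs in the female libraries of every cluster and lay at 181 to 289 CPM in the male ones, and Uty, a histone demethylase gene (chromosome Y from 1096861 to 1245759), lay at 0 to 3.21 CPM and 148 to 205.0 CPM. The 4 Y-linked genes passed in 9 of the 11 clusters and 3 of them in the other 2. Beyond the Y-linked list, 18 genes were higher in males in every cluster, among them the growth factor receptor gene Fgfr2 (log2 fold -2.30 to -1.74; 172 to 335 CPM in females, 793.5 to 1119 in males), the ubiquitin ligase gene Ube3a (-1.74 to -1.44), the transcription factor gene Mef2c (-2.98 to -1.51), the DNA repair gene Xrcc6 (-2.55 to -2.08) and mt-Nd4l, a mitochondrially encoded subunit of complex I (-3.89 to -3.43; 46.6 to 82.04 CPM and 669 to 977). Of these 18, 12 (66.7%) overlap another gene of the files on the opposite strand, against 20.9% of other genes tested in neurons. With any annotated gene it was 14 (77.8%), against 46.4%. Ube3a overlaps Snhg14 by the annotation only, Xrcc6 overlaps Desi1, and Fgfr2 spans 16 such genes, so without strand their counts are uncertain. The highest adjusted p of Fgfr2 over the clusters was 2.633e-04.

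Genes higher in females were fewer than those higher in males in each of the 11 clusters other than cluster 3. Nap1l5, an imprinted nucleosome assembly gene that lies within Herc3 on the other strand, was higher in females in 10 of 11 clusters (log2 fold 0.97 to 1.79; 216 to 366 CPM against 82.6 to 159), the kinase gene Matk in 8 (0.80 to 1.66), Rtn1 in 6 (1.00 to 1.42), and Atp6v1g2 and the chaperone gene Hspa5 in 5 each. Kdm6a, an X-linked histone demethylase gene (chromosome X from 18162575 to 18279936), lay at 90.8 to 133.5 CPM in females and 55.9 to 89.2 in males and passed in 0 of 11 clusters by edgeR (adjusted p = 0.0801 to 0.977). Of the same list Ddx3x and Kdm5c each passed as higher in females in 1, cluster 3 (adjusted p = 0.0284 and 0.0411). Counts per cluster differed. Cluster 3, an inhibitory cluster led by Fibcd1 and Ntng1, gave 1287 genes of 10218, 669 higher in females and 618 in males, by edgeR and 117 by DESeq2 (16 and 101). The other 10 clusters gave 36 to 175 genes, with 0 to 19 higher in females. In cluster 22, the one with 0, 201 were higher in females at an unadjusted p under 0.05 and DESeq2 called 0. In all, 1328 genes passed in at least 1 cluster, 102 were higher in males in 5 or more, 5 were higher in females in 5 or more, and 0 passed in both directions.

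Summed over the class, 451 of 12606 genes passed in excitatory neurons, 34 higher in females and 417 in males, and 491 of 12990 in inhibitory neurons, 33 and 458. These sums include the clusters led by another class's markers. These clusters held 46.6 and 47.7% of the excitatory neurons of the male libraries and 1.37 to 3.58% of those of the female libraries, and 40.8 and 42.9% against 24.9 to 34.0% of the inhibitory neurons. Each of these clusters failed the marker check on 1 gene. For clusters 2 and 7 it was Chat, which was itself higher in the male libraries, so the check may leave out nuclei by library. Without clusters 1, 2, 7 and 21, 346 and 401 genes passed. In excitatory neurons Eif2s3y had 0 UMIs among 14023577 female UMIs and 205 ± 5.27 CPM in males, at least 957-fold higher against 3 counts over the female libraries. Uty lay at 1.40 ± 1.26 and 163 ± 0.93 CPM and Ddx3y at 0.851 ± 1.48 and 65.5 ± 5.61 CPM. Kdm5d lay at 0.394 ± 0.387 and 49.5 ± 3.66 CPM. The monocarboxylate transporter gene Slc16a4 (chromosome 3 from 107291230 to 107312115, with no partner on the other strand) was at 5.37 ± 0.455 CPM in females and 68.2 ± 7.12 CPM in males (log2 fold -3.64 ± 0.19, adjusted p = 0.00183). Ggact (-2.46 ± 0.14), Shisa3 (-3.26 ± 0.18) and Gm21954 (-3.39 ± 0.20) were also higher in males, and each overlaps another gene on the other strand. Higher in females were Nrbp2 (110 ± 5.17 against 47.7 ± 3.06 CPM, 1.2 ± 0.14), Matk (248 ± 34.2 against 96.8 ± 6.62 CPM, 1.35 ± 0.16) and Vamp2, a synaptic vesicle gene (72.9 ± 3.13 against 35.9 ± 2.96 CPM, 1.02 ± 0.15). In inhibitory neurons Ccdc73 (-2.69 ± 0.15) and Tifa (-2.94 ± 0.17) were higher in males, and Smim10l1 (1.41 ± 0.20) and Ypel3 (1.25 ± 0.18) in females.

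The class counts rested on single libraries. Female library 1 lay between the males and the other females in its mitochondrial share. As the only Chat-Cre library, it left genotype unbalanced between the sexes. Without it, 4791 genes passed in excitatory neurons (2435 higher in females and 2356 in males) and 5228 in inhibitory neurons (2708 and 2520). In every comparison without it, sex went together with mitochondrial share. Among nuclei kept, the median share was 0.202 and 0.237% in female libraries 2 and 3 and 2.56 and 2.61% in the males. These counts are therefore not those of sex alone. Without female library 2, 215 and 243 genes passed, and without female library 3, 218 and 233 did. Without male library 1, when the lone male was assumed to vary like the females, 8 and 2 passed. The 8 included Uty, Eif2s3y, Slc16a4, Shisa3, Ggact, Gm21954 and Fgfr2. Without male library 2 it was 0 and 2 by edgeR, with 889 excitatory genes at an unadjusted p under 0.05, and the excitatory adjusted p of Uty, Eif2s3y, Slc16a4 and Fgfr2 was then 0.0623. Leaving out female library 2 or 3 also ended the calls of Vamp2 in excitatory neurons (0.0692 and 0.0603; 2.344e-06 to 0.313 over the alternatives) and of Ypel3 in inhibitory neurons (0.0682 and 0.0631; 1.101e-11 to 0.295), and leaving out female library 2 that of Smim10l1 (0.06; 5.161e-11 to 0.26).

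Among the gene lists, the Y-linked list passed in both neuron classes, 4 of 4 genes each (camera adjusted p = 1.386e-57 and 3.456e-70, and adjusted p = 0.0111 and 0.00824 with an estimated correlation). The X-linked genes that escape inactivation did not pass by edgeR, 0 of 6 in each class, with 2 higher in females at an unadjusted p under 0.05 in each, 0 and 1 by DESeq2, and 1 and 1 adjusted over the list alone. Kdm6a was at 100 ± 3.26 against 70.6 ± 2.53 CPM in excitatory neurons (log2 fold 0.50 ± 0.13, adjusted p = 0.0967; 3.131e-04 to 0.786 over the alternatives) and 113 ± 5.45 against 74.2 ± 8.84 CPM in inhibitory ones (0.60 ± 0.14, 0.0809). The adjusted p of Ddx3x was 0.259 and 0.3, of Eif2s3x 0.363 and 0.29, of Kdm5c 0.53 and 0.633, of Pbdc1 0.946 and 0.79 and of Utp14a 0.928 and 0.559. Without female library 1, when sex went together with mitochondrial share, Kdm6a (0.00113 and 5.798e-05), Kdm5c (2.379e-05 and 7.308e-05) and Ddx3x (0.0169 and 0.00194) passed by edgeR. The highest values over the alternatives were 0.571 for Kdm6a in inhibitory neurons and, in the 2 classes, 0.962 and 0.998 for Kdm5c and 0.80 and 0.887 for Ddx3x. The mitochondrially encoded list was lower in females by camera (adjusted p = 5.769e-05 and 9.806e-06), a call lost with an estimated correlation (adjusted p = 0.852 and 0.728). In excitatory neurons it was also lost with a term for the low mitochondrial share of female libraries 2 and 3 (0.0769; the lowest over the alternatives was 2.447e-94). Of its 12 genes only mt-Nd4l passed (57.3 ± 23.8 against 735 ± 56.4 CPM and 65.5 ± 20.2 against 831.5 ± 100.4 CPM), and 2 did adjusted over the list alone. Its position next to mt-Nd4 on the same strand leaves its counts uncertain, and nuclei had been filtered on these genes' share.

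Stress and rhythm genes gave weaker or unstable results. In the heat shock list Hspa5, a chaperone of the endoplasmic reticulum, was the only gene to pass in either class (265 ± 17.3 against 143 ± 29.6 CPM, log2 fold 0.89 ± 0.17, and 323.5 ± 12.4 against 167 ± 39.4 CPM, 0.95 ± 0.17), of 9 and 10 measured. Adjusted over the list alone it was 2 and 1. Its adjusted p of 0.041 and 0.0408 rose to 0.12 and 0.116 without female library 2, 0.102 and 0.123 without female library 3, 0.374 and 0.33 without male library 1, and 0.177 and 0.157 without male library 2 (lowest over the alternatives 5.327e-06 and 1.058e-04). The list itself missed the threshold (camera adjusted p = 0.0557 and 0.0849) and passed without female library 2 (0.0135 and 0.011) or 3 (0.00401 and 0.0218; 2.23e-06 to 0.35 and 1.287e-05 to 0.383 over the alternatives). The circadian list passed by camera in excitatory neurons (adjusted p = 0.0391), where 0 of 15 genes passed by edgeR, 3 were higher in females at an unadjusted p under 0.05 and DESeq2 called 1. That call was lost with an estimated correlation (adjusted p = 0.852), without female library 3 (0.108) and without male library 1 (0.0617), and over the alternatives it ran from 0.0123 to 0.531. In inhibitory neurons the list did not pass (0.0897), and its 1 gene past the threshold, the clock output gene Dbp (44.4 ± 1.196 against 26.3 ± 1.194 CPM, 0.76 ± 0.15, adjusted p = 0.0491; 4.853e-05 to 0.529 over the alternatives), overlaps Sphk2 on the other strand and lost its call without any 1 of female library 2 (0.183), female library 3 (0.151), male library 1 (0.361) or male library 2 (0.529). Of immediate early genes 0 of 12 and 0 of 13 passed by edgeR (camera adjusted p = 0.175 and 0.103), with 2 and 3 higher in females unadjusted and 0 by DESeq2. Of sex steroid receptors 0 of 6 passed in each (0.501 and 0.657), with 3 and 1 past the unadjusted threshold, 0 and 1 by DESeq2, and 0 and 1 adjusted over the list alone.

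Of the remaining lists, the glucocorticoid response list gave 0 of 9 in both classes by edgeR (camera adjusted p = 0.938 and 0.744; 2 unadjusted in each, 0 by DESeq2), with a median log2 fold of 0.22 and a mean of -0.09 in excitatory neurons. Cytosolic ribosomal protein genes gave 0 of 43 in each (0.727 and 0.657; 7 and 13 unadjusted, 2 and 4 by DESeq2); their medians were -0.06 and -0.08, as in camera's direction, and their means 0.23 and 0.22. Nuclear oxidative phosphorylation genes gave 0 of 21 in each (0.938 and 0.963; 2 and 1 unadjusted, 0 and 1 by DESeq2). The X inactivation RNAs were not measured, and of the nuclear-retained RNAs 1 of 8 was measured and 0 passed by edgeR or DESeq2. Of the 13 neuronal lists none passed by camera; the lowest adjusted p was 0.194 for GABA and glycine receptors in excitatory neurons and 0.103 for neuropeptides in inhibitory neurons. Without female library 1 the neuropeptide list passed in both classes (0.0225 and 5.648e-04) and the transcription factor list in excitatory neurons (0.0155), without male library 1 the neuropeptide list passed in inhibitory neurons (0.0343), and without female library 3 the calcium-binding protein list did there (0.03). The highest values over the alternatives were 0.847 and 0.473 for neuropeptides, 0.934 for transcription factors and 0.932 for calcium-binding proteins. Their members past the threshold were Mef2c (45.3 ± 9.76 against 258 ± 7.61 CPM and 94.8 ± 10.6 against 405 ± 47 CPM) and the sodium channel gene Scn9a (92.5 ± 11.9 against 348 ± 64.4 CPM and 54.8 ± 3.4 against 343 ± 64.1 CPM) in both classes, all higher in males. Oprm1 (73.1 ± 7.18 against 127 ± 4.02 CPM, -0.80 ± 0.14) and the synaptic adhesion gene Lrrtm1 (37.6 ± 8.57 against 80.9 ± 3.46 CPM, -1.12 ± 0.22) passed in inhibitory neurons only, and both overlap other genes. Adjusted over the list alone, inhibitory neurons gave 1 transcription factor gene higher in females and 2 in males and 2 synaptic adhesion genes higher in males. Oprm1 and Lrrtm1 lost their calls without female library 2 (adjusted p = 0.125 and 0.109), female library 3 (0.0828 and 0.0939), male library 1 (0.291 and 0.328) or male library 2 (0.40 and 0.456), with lowest values of 1.29e-08 and 4.107e-12 over the alternatives.

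In glia the differences called by edgeR with every library ran in one direction, which did not hold without female library 1. In astrocytes 47 of 9864 genes passed, 47 higher in males. Chst9, a sulfotransferase gene (chromosome 18 from 15451924 to 15760157), was at 10.7 ± 2.64 CPM in females and 237 ± 14.5 in males (log2 fold -4.50 ± 0.27, adjusted p = 0.00193), Gsdme, which encodes a pore-forming gasdermin, at 312 ± 35.6 and 1299 ± 108 CPM (-2.06 ± 0.15), and Fgfr2 at 407 ± 22.2 and 1194 ± 131 CPM (-1.55 ± 0.13). In oligodendrocytes 22 of 8869 passed, 22 higher in males. Galnt5 was at 24.0 ± 5.96 and 326 ± 33.6 CPM (-3.76 ± 0.29), Xrcc6 at 89.9 ± 20.2 and 906 ± 184 CPM (-3.33 ± 0.27) and Fbxw15 at 47.3 ± 15.9 and 559 ± 146 CPM (-3.55 ± 0.33). Gsdme, Gm21798 (-3.31 ± 0.28 in astrocytes), Galnt5, Fgfr2 and Xrcc6 overlap other genes on the opposite strand. Higher in females were 0 in each by edgeR, with 373 and 285 at an unadjusted p under 0.05 and 6 and 2 by DESeq2, which called 101 and 72 genes in all.

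The glial counts also rested on single libraries and on clusters that differed between them. Female libraries 2 and 3 supplied most oligodendrocytes of cluster 8, and female library 1 and the males those of cluster 12. With a term for the low mitochondrial share of female libraries 2 and 3, calls were made in both directions. The sex difference was then that of female library 1 alone against the male libraries. Without female library 1, 989 genes passed in astrocytes (469 higher in females and 520 in males) and 793 in oligodendrocytes (379 and 414). Without female library 2 it was 8 and 6, without female library 3 it was 9 and 6, without male library 1 it was 2 and 0, and without male library 2 it was 0 and 0 by edgeR, with 441 astrocyte and 401 oligodendrocyte genes unadjusted (449 for oligodendrocytes without male library 1). The 2 astrocyte genes were Uty and mt-Nd4l. Fgfr2 in astrocytes lost its call without female library 2 (0.081) or 3 (0.0614; 5.449e-11 to 0.347 over the alternatives), and Fbxw15 likewise (0.0587 and 0.062; 4.508e-13 to 0.455). The Y-linked list passed in both (camera adjusted p = 4.145e-56 and 4.881e-46, adjusted p = 0.0148 and 0.0137 with an estimated correlation), with 3 and 2 of 4 genes past the threshold and 4 and 4 adjusted over the list alone. Eif2s3y had 0 female UMIs in both (181.5 ± 6.701 and 180.0 ± 1.68 CPM in males, at least 216-fold and 134-fold higher), Uty lay at 0.955 ± 0.377 against 220 ± 27.4 CPM and 0.869 ± 0.768 against 194 ± 24.6 CPM, and Kdm5d in astrocytes at 0 against 51.5 ± 1.93 CPM, at least 61.2-fold higher. Ddx3y (adjusted p = 0.197 and 0.192) and, in oligodendrocytes, Kdm5d (0.0591) missed the threshold and passed without female library 1 (2.099e-07 and 7.621e-06 for Ddx3y, 8.246e-05 for Kdm5d; up to 1.0 and 0.146 over the alternatives). The Kdm5d call in astrocytes was lost without female library 2 (0.0941), female library 3 (0.0614), male library 1 (0.641) or male library 2 (0.933), and reached 2.416e-08 in another alternative.

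Of the X-linked genes that escape inactivation 0 of 6 passed by edgeR in each glial class (camera adjusted p = 0.145 and 0.652; 1 and 0 unadjusted, 0 by DESeq2), with Kdm6a at 171 ± 12.6 against 108 ± 27.9 CPM in astrocytes (log2 fold 0.65 ± 0.22, adjusted p = 0.48) and 290.5 ± 46.6 against 197 ± 37.0 CPM in oligodendrocytes (0.56 ± 0.26, 0.739). Without female library 1 Kdm6a passed in both (0.0197 and 0.0272) and Kdm5c in astrocytes (0.042), and without male library 2 the list passed in astrocytes (0.0399; up to 0.567 over the alternatives). For Kdm6a and Kdm5c the adjusted p reached 1.0 in other alternatives. The mitochondrially encoded list was lower in females (2.373e-16 and 1.072e-15, adjusted p = 0.719 and 0.608 with an estimated correlation), with mt-Nd4l the 1 gene of 12 past the threshold (103 ± 4.31 against 998 ± 134 CPM and 129 ± 9.03 against 1101 ± 132 CPM) and 2 adjusted over the list alone. For the other lists camera gave an adjusted p in astrocytes and oligodendrocytes of 0.887 and 0.749 for immediate early, 0.407 and 0.839 for circadian clock, 0.407 and 0.319 for heat shock, 0.407 and 0.565 for glucocorticoid response, 0.137 and 0.691 for ribosomal protein and 0.424 and 0.749 for nuclear oxidative phosphorylation genes. Sex steroid receptors gave 0.993 in astrocytes, with 1 gene measured in oligodendrocytes. The neuronal lists gave 0.407 to 0.993 and 0.229 to 0.948. Of the list genes outside the Y-linked and mitochondrial lists, 0 passed by edgeR in each class, with 26 and 20 at an unadjusted p under 0.05 and 0 and 1 (Lrrtm3, lower in females) by DESeq2. Ribosomal protein genes, with negative medians (-0.28 and -0.14) and positive means (0.18 and 0.39), had 9 and 7 unadjusted and 0 by DESeq2, and the list passed in astrocytes without female library 1 (0.0108), 2 (1.257e-04) or 3 (5.689e-04) or male library 2 (6.141e-04; 1.374e-07 to 0.777 over the alternatives). Without female library 1 the lists of nuclear oxidative phosphorylation and of sodium, calcium and HCN channels also passed in astrocytes (0.0315 each; up to 0.869 and 0.982 over the alternatives). In oligodendrocytes it passed without female library 2 (0.0418) and the heat shock list without female library 3 (0.024); over the alternatives they reached 0.96 and 0.959. In oligodendrocytes 2 glucocorticoid response genes were higher in females adjusted over the list alone, and 1 monoamine receptor and 1 synaptic adhesion gene in males.

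The sex difference was compared between excitatory and inhibitory neurons by the interaction term. It passed for 15 of 13336 genes, 6 with a difference more toward females in excitatory neurons and 9 in inhibitory neurons, with 860 at an unadjusted p under 0.05. Oprm1 differed by 0.63 ± 0.12 on the log2 scale (adjusted p = 0.049): its log2 fold was -0.20 ± 0.15 in excitatory and -0.80 ± 0.14 in inhibitory neurons. Scn9a differed by 0.70 ± 0.09 and Chst9 by 1.48 ± 0.17, with Chst9 at 78.9 ± 12.2 against 69.3 ± 6.47 CPM in excitatory and 7.72 ± 1.55 against 18.7 ± 0.435 CPM in inhibitory neurons. In the other direction were the serotonin receptor gene Htr2c (-0.68 ± 0.10) and Grm3 (-0.46 ± 0.08). These examples were chosen after their values were seen. The count was 345 without female library 1 and 10 without female library 2, and DESeq2 called 4 genes. Few of the 15 were called again in some alternatives: 3 by DESeq2, 5 without clusters led by another class's markers, 5 with each library clustered alone and 4 without male library 2.

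Chat, the enzyme that makes acetylcholine, is named in the genotypes and was therefore measured in every library. Its level over all nuclei was 0.247 CPM in female library 1, 20.8 and 25.4 CPM in female libraries 2 and 3, and 166 and 206 CPM in the male libraries (chromosome 14 from 32408203 to 32465989, minus strand). At least 1 Chat UMI was found in 0.0701% of nuclei of female library 1 (95% interval 0.0321 to 0.153), 4.75% (4.19 to 5.38) and 5.23% (4.64 to 5.90) in female libraries 2 and 3, and 23.02% (21.9 to 24.2) and 35.5% (34.3 to 36.9) in the male libraries. Thinned to 1000 UMIs, the shares were 0, 2.09, 2.59, 15.3 and 18.8%. In male library 1 Chat UMIs were in 34.6% of excitatory and 21.1% of inhibitory neurons and 4.52% of astrocytes, at median depths of 1961, 1579 and 814 UMIs. In female library 1, 0 of 3823 inhibitory neurons had one, which allows a share with a UMI of up to 0.0785% and sets no limit on nuclei that express the gene. Slc5a7, the choline transporter of cholinergic neurons, was found in 0.105, 0.183, 0.187, 0.128 and 0.115% of nuclei. Slc18a3, the vesicular acetylcholine transporter, lies inside Chat on the same strand and is listed at 0 UMIs in every library. How reads shared by overlapping genes were counted is not given in the sources used here, so its expression is left uncertain.

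Genes beside Chat were measured in the same way. 1700024G13Rik, 19812 bases away on the same strand, had 0 UMIs in female library 1, 23.3 and 25.1 CPM in female libraries 2 and 3 and 118 and 117 CPM in the male libraries. Ercc6, a DNA repair gene 47532 bases away on the plus strand, lay at 31.5 CPM in female library 1 and at 109.5, 121, 108 and 117 CPM in the other 4. Ogdhl, 60052 bases away, lay between 18.5 and 27.1 CPM in all 5. Female library 1 is the only one of its genotype, so this difference has no replicate check.

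**Figure D3:**
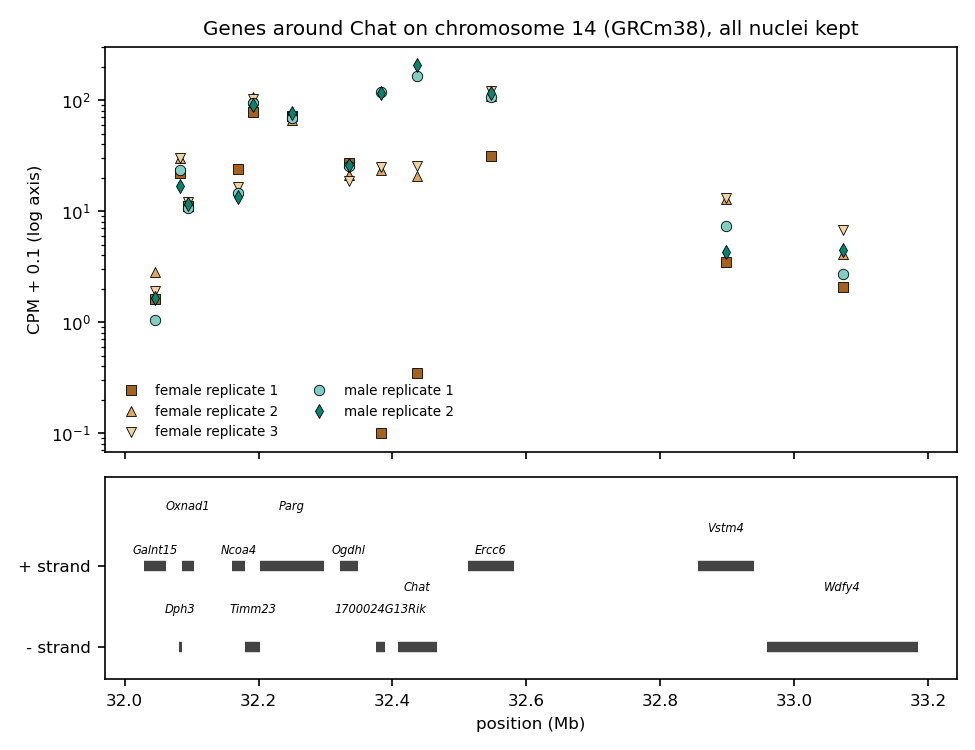
Levels of genes around Chat on chromosome 14 (y axis, CPM with 0.1 added, log axis; x axis, position in Mb) in all nuclei kept, 1 point per library, above a map of the genes and their strands. Chat lay at 0.247 CPM in female library 1 and at 206 CPM in male library 2, and Ogdhl between 18.5 and 27.1 CPM.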

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

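Most tests in this part were chosen after the result was seen: the share of genes with an opposite-strand neighbour, the grouping of the libraries, the copies of the Chat locus, the search for cholinergic neurons and both tests on shared barcodes. The tests on the level of the opposite-strand neighbour and on the share of X and Y genes were written before their results were seen.

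With every library, most genes called between the sexes were higher in the male libraries in each of the 4 classes, Fgfr2 and Ggact in excitatory neurons among them; without female library 1 it was 2435 higher in females and 2356 in males in excitatory neurons. Of those called in excitatory neurons, 53.3% overlap another gene of the files on the other strand (220.0 of 413, against 20.4% of other genes), and over overlapping genes the female-to-male difference fell with the level of the neighbour relative to the gene's own (rho -0.324, bootstrap interval -0.359 to -0.288; -0.114 with the nearest gene where none overlapped). UMIs read from the opposite strand in the male libraries may account for part of them, though not for genes without such a neighbour, such as Slc16a4 and Mef2c. The libraries were also grouped other than by sex. With female libraries 2 and 3 set against the other 3, 1574 genes were called in excitatory neurons, more than the 451 of the sexes. The other 8 splits of this kind gave 0 by edgeR. That grouping puts female library 1 with the males, so alone it cannot account for genes that separate female library 1 from them. The calls kept with a term for that grouping are given below. Sex itself stays open, since each male library is also of the group with a high mitochondrial share: 3.80% of the calls outside the Y-linked list lie on X or Y (17 of 447, 95% interval 2.39 to 6.01), against 3.56% of other genes, which cannot be told apart from no effect of the sex chromosomes.

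Chat and 1700024G13Rik were higher in every Chat-GFP library than in female library 1, and within that genotype Chat was higher in the males than in female libraries 2 and 3 (log2 ratio 2.96), while Ercc6 was not (-0.04). Extra copies of the locus cannot be told apart from other explanations: the other 2 genes within 100 kb, Ercc6 and Ogdhl, had log2 ratios of 1.84 and -0.44 between female libraries 2 and 3 and female library 1 (median 0.70), against a median of 0.39 for 8 genes at 100 to 500 kb. Slc5a7, the choline transporter gene, could not tell cholinergic neurons apart either. Of the 3596 nuclei of these libraries with a Chat UMI, 0.0278% also had an Slc5a7 UMI (1 nucleus, 95% interval 0.00491 to 0.157%). Of those without, 0.178% had one, so Slc5a7 was near the detection limit in both and not more frequent beside Chat. In male library 1, as given above, Chat UMIs lay in excitatory neurons, inhibitory neurons and astrocytes, so they were not confined to a single class. Genotype and library are the same thing for female library 1, and no biological explanation beyond cholinergic neurons was tested.

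Female libraries 2 and 3 shared 409 barcodes, an overlap that no comparison measured. That is 15.8 ppm of all pairs of their barcodes, against at most 0.431 ppm in the other 9 pairs of libraries, so overlap by chance alone is argued against. Of the 409, 399 had a UMI total in one library of 0.08 to 0.15 times the other, a window set after the ratios were seen (median ratio 0.108; smaller in female library 2 for 406), and 75.9% of these 399 had a female library 2 profile closest to that of the same barcode in female library 3, against 0.251% by chance. Of the 399, 363 were among the nuclei kept of female library 2 and so entered the comparisons. RNA or reads of the same nuclei present in both libraries may account for this, though how it came about stays open and no biological explanation was tested.

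Of the nuclei of female library 1, 0.783% lay in the hemoglobin-led cluster, far from the other 4 libraries, where the share was 0.0415% or less. The share so named depends on the clustering: it was 0.672 ± 0.0999% in females and 0.452 ± 0.148% in males at resolution 2.0, and 0.362 ± 0.627% and 1.02 ± 0.697% with each library clustered alone. The sex difference differed between excitatory and inhibitory neurons for 15 genes, by the test of that difference itself. The mitochondrial share left 22227 barcodes out of the comparisons other than those without the filter, most of them from the male libraries.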

How the results depend on the processing

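Alternatives chosen after the data were seen were those without the mitochondrial filter, without shared barcodes, with genes centred within libraries, with each library clustered alone, without clusters led by another class's markers, with a low mitochondrial share as a term, and the tests by cluster number. For the cause of each change below, the cause was not tested, except that thinning lowers the counts and that leaving out a library lowers the number of samples.

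Of 4569 genes that differed between excitatory and inhibitory neurons, DESeq2 called 2687, a model with no block for the library 1231 and nuclei thinned to 1000 UMIs 2846, of which 2662, 1229 and 2685 were among the 4569; the other counts were 3749 to 4998. Of 1577 values of named genes, 1558 kept their direction and call, 18 lost the call and 1, Cacna2d3, turned to 0.23. Of 234 values of lists 214 kept both; the transcription factor list turned without doublet removal (0.949) and without female library 2 (its range without single libraries was 0.00377 to 0.935). The real grouping was the only 1 of 100 drawn splits of the 10 sums with as many genes, against 2 in the highest other. As the sums were formed by clustering on expression, mixed splits give few genes by construction, and this leaves chance untested.

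The sex comparison in excitatory neurons (451) gave 251 genes when thinned and 3458 with the mitochondrial term, and 0 to 4791 without single libraries. In inhibitory neurons (491) it gave 758 by DESeq2, 314 when thinned and 4305 with the term, and 2 to 5228 without single libraries. In astrocytes (47) it gave 101 by DESeq2, 93 with no filter, 5 at 800 genes per nucleus, 15 when thinned and 1780.0 with the term, and 0 to 989 without single libraries. In oligodendrocytes (22) it gave 72 by DESeq2, 85 with no filter and 1356 with the term, and 0 to 793; the comparisons at 800 genes and thinned were not run there for want of nuclei. With the term 1553, 1994, 1011 and 752 of these were higher in females, and without female library 1 it was 2435, 2708, 469 and 379. The term kept 450 of the 451, 489 of the 491, 47 of the 47 and 22 of the 22 calls. With it, lists that had not passed turned direction and passed (adjusted p): sodium, calcium and HCN channels in astrocytes (0.0067) and oligodendrocytes (0.00121), synaptic adhesion in both (0.024 and 3.368e-05) and ionotropic glutamate receptors in oligodendrocytes (0.0156). Of the lists in excitatory and inhibitory neurons 392 of 414 and 401 of 414 values kept direction and call.

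The interaction (15) gave 4 by DESeq2, 79 with no filter, 24 without the mitochondrial filter, 25 without shared barcodes, 8 with each library clustered alone, 30 without clusters led by another class's markers, and 10 to 345 without single libraries.

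Class shares kept within 1 SD in 72 of 78 values. The excitatory share was 11.3% without the mitochondrial filter; the inhibitory share 34.1% without doublet removal, 48.5% at 800 genes per nucleus and 30.04% without the mitochondrial filter. At 800 genes the oligodendrocyte share was 2.65% and the microglia share 1.13%. The share test passed 4 of 8 classes at 800 genes, 2 of 12 without the mitochondrial filter, 2 of 6 with each library clustered alone and 0 to 10 without single libraries, and the astrocyte ratio was then 1.14 to 1.27.

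Whether the numbers in the labels pair the samples was not settled. The same-number correlations were -0.12 and -0.132 in excitatory and -0.139 and -0.161 in inhibitory neurons. They were 0.03 and -0.011 in astrocytes and -0.0012 and -0.0063 in oligodendrocytes. With 2 male libraries centred on their mean, a correlation with one male library is that with the other with its sign turned. This check therefore cannot exclude pairing. A replicate block gave 347, 601, 43 and 12 genes in the 4 classes, passed 0 of 10 classes in the share test by edgeR (astrocytes 1.22, adjusted p = 0.495) and moved no count over 1.5 times other than that of oligodendrocytes. It ended the calls of Vamp2 and Hspa5 and of the circadian list in excitatory neurons and of Dbp, Hspa5 and Oprm1 in inhibitory neurons. It added Ddx3x in inhibitory neurons, the heat shock list in neurons and astrocytes, the calcium-binding protein list in inhibitory neurons and astrocytes and the GABA and glycine receptor list in oligodendrocytes, and changed no other call of a named gene or list.

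Depth limits what thinning could keep: of the calls, 2685 of 4569, 233 of 451, 286 of 491 and 14 of 47 were made again at 1000 UMIs in the neuron comparison and in the sexes in excitatory neurons, inhibitory neurons and astrocytes.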

Other observations

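The tests and examples in this part were chosen after the values were seen. Single genes of other neuronal lists also stood high in particular subclusters. The calcium channel subunit gene Cacna2d1 was highest in E4 (3289 ± 167 CPM, n = 5 libraries, against 77.2 in the median subcluster), the sodium channel gene Scn3a in E5 (908 ± 28.6 CPM), and the potassium channel gene Kcnq5 in E6 (1985 ± 258 CPM). Among inhibitory subclusters, the serotonin receptor gene Htr2c was highest in I12 (3244 ± 496 CPM, median subcluster 160), Grm3 and Glra2 both in I21 (2149 ± 336 and 606 ± 134 CPM), the cell adhesion genes Nxph1 in I9 (4136 ± 174 CPM) and Cdh6 in I24 (1765 ± 483 CPM), and the ephrin receptor gene Epha3 in I18 (1164 ± 114 CPM). No test was run over subclusters.

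In microglia-like nuclei (cluster 24) 346 of 4807 genes passed between the sexes by edgeR, 179 higher in females and 167 in males; DESeq2 called 81 and 101. Higher in males were, for example, the calcium-binding protein gene Aif1 (361 ± 125 against 15.8 ± 7.01 CPM, log2 fold -4.33, adjusted p = 0.00254), the complement gene C1qb (5953 ± 1957 against 1634 ± 181 CPM, -1.86) and the chemokine receptor gene Cx3cr1 (3291 ± 49.8 against 822 ± 281.5 CPM, -2.01). Higher in females were, for example, the synaptic adhesion gene Lrrtm4 (1588 ± 468 against 327 ± 17.6 CPM, 2.27), Nxph1 (2.71), the active zone gene Rims1 (521 ± 79.5 against 106 ± 38.3 CPM, 2.25) and the synaptic vesicle gene Syp (347.0 ± 53.2 against 87.6 ± 50.9 CPM, 2.07, adjusted p = 0.0114). Among the markers of neurons, Rbfox1 (2516 ± 220 against 1091 ± 96.5 CPM, adjusted p = 0.0122) and Syt1 (1294 ± 108.5 against 678 ± 148 CPM, adjusted p = 0.0379) were higher in females by edgeR. Not called were Slc17a6, at 114, 57.6 and 116 CPM in females and 27.1 and 30.7 CPM in males, and Gad1, at 296, 144 and 92.7 CPM and 45.2 and 61.4 CPM. Whether RNA of neurons in the microglia-like nuclei differed between libraries was not tested, so these calls cannot be assigned to microglia themselves. In oligodendrocyte precursor-like nuclei (cluster 18) 42 of 5075 genes passed, 1 higher in females and 41 in males. Beyond DESeq2, no alternative was run for clusters 24 and 18, and no library was left out in turn.

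Libraries resembled each other by pairs rather than by sex alone. Over excitatory neurons the correlation was 0.981 between female libraries 2 and 3 and 0.986 between the male libraries. Female library 1 correlated with the males at 0.944 and 0.943 and with the other females at 0.932 and 0.932, and female library 2 with the males at 0.906 and 0.898.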
